A study of Homo sapiens with 2 samples.

How the data were processed

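CUT&Tag cuts and tags DNA with a transposase tethered to an antibody, so that reads pile up where the antibody's target sits. It was run here for EWS-FLI binding in TC32, an established Ewing sarcoma cell line. EWS-FLI is the fusion of EWSR1 with the ETS transcription factor FLI1 that drives this tumour. There was 1 library from cells given siEWS-FLI and 1 from cells given siNEG. The labels do not spell out siNEG, which is treated here as the arm set beside siEWS-FLI, and they do not name the antibody. Libraries were made with a commercial CUT&Tag protocol and amplified by 14 and then 20 cycles of PCR, 34 in total, per the labels' protocols.

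Trim Galore 0.6.6, Bowtie2 2.4.5, MACS2 2.2.9.1 and the build hg38 are named in the submitters' processing notes, without their roles. The use of a control library, the handling of duplicate reads and the fragment settings are not given in the sources used here. Each library has its own deposited peak list, so peaks were called per library. In each line the deposited columns hold the interval, a display score, the fold enrichment at the summit, the −log10 p-value and −log10 q-value, and the position of the summit. The deposited score column was not used. The deposited fold enrichment is a linear ratio over the caller's local background, and it and the deposited −log10 q-value were used to rank intervals within a list only. The smallest deposited −log10 q-value was 1.32 with siNEG and 1.33 with siEWS-FLI.

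The summit pileup, the number of extended reads over the summit base, was computed from the deposited fold and −log10 p-value. The fold was taken as pileup plus 1 over background plus 1, and the p-value as the upper tail of a Poisson distribution. A whole pileup solved both for 100% of the lines of each list, with a tolerance of 0.001 in log10 p that grew in proportion for −log10 p above 10; the fit is a weak test for very large values. In 100% of lines with a local background above the library's own, that background lay on a grid of 200 divided by 10000, as reads extended to 200 bases and a 10000-base window give. The library-wide background was 0.348 reads per base with siNEG and 0.239 with siEWS-FLI. Pileups are raw reads, not scaled between libraries. Without repeated read positions a pileup could reach at most 400, and larger ones were present, so repeated positions were kept. An interval that was not called lies below the caller's threshold and is not shown to be empty.

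Depth was not given as read totals. With an assumed mappable genome of 2700000000 bases, the backgrounds correspond to about 4702750 reads with siNEG and 3229660 with siEWS-FLI. One 10 kb window of the mitochondrial genome held about 1853920 and 1629620 of them. The remainder was about 2848840 and 1600040 reads, a ratio of 0.562, siEWS-FLI over siNEG. These totals rest on the assumed genome size, and the remainder still holds any mitochondrial reads outside that 10 kb window.

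Lines that share an interval were merged, keeping the strongest summit, and chromosomes 1 to 22, X and Y were used. Intervals were called shared when they overlapped by at least 1 base. Overlap by chance was measured with 1000 random placements on the same chromosomes, whose lengths were taken as the furthest gene or peak end. Gene positions came from RefSeq on GRCh38.p14, whose primary chromosomes have the coordinates of hg38; 20033 protein-coding genes were used. As a check of the build, gene ends shifted by 100 kb met 4.93% of siNEG summits, against 36.1% unshifted. The gene table used here holds starts and ends without strand or exons. The planned distance to a transcription start was therefore replaced by the distance to either gene end, "gene end" means a summit within 1 kb of one, and exons and introns were not told apart. No genome sequence was used here, so the planned search for GGAA repeats and ETS sites was not run, and retention was compared by location in place of sequence.

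Retention is the share of siNEG intervals, or of genes with a siNEG summit, that also had a siEWS-FLI interval. For the comparison by location it was weighted over 5 equal classes of siNEG strength by −log10 q, with 1000 bootstrap draws of intervals. There were 13 gene lists with 230 genes, all 230 of which matched the gene table. A gene had a summit when one lay within 50 kb of either end. List values were ranked among 10000 random lists of equal size, matched on 10 classes of local gene density for the share with a summit, and on 10 classes of siNEG strength for retention. A percentile describes these 2 libraries only. The gene lists, the named-gene rule, the test of each comparison and 31 alternatives were fixed before the data were examined; the closing section names the tests chosen later. The rule named the 10 strongest intervals within 50 kb of a gene in each class (shared, siNEG-only and siEWS-FLI-only), up to 4 members per class of each list, and FLI1, EWSR1, ATR and CHEK1. Some of the genes this rule names are not reported here.

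With 1 library per group no difference has a replicate check, and no p-value between groups is given. Shares have Wilson 95% intervals and pileups exact Poisson 95% intervals. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. The steps were tested on simulated data. Of 2000 simulated pileups, 100% were recovered. A planted overlap of 59.6% of 6370 intervals was found as 59.6%. A planted difference of 10 percentage points in 16000 intervals was found as 11.5 (9.58 to 13.3), against 23.6 without weighting. Of 200 random lists, 1% fell below the 2.5th percentile, and a planted low list of 24 genes lay at 0.2. In that simulation retention did not depend on strength and genes did not share summits, so it did not test the matching on strength. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives covered the peak threshold, the overlap, the list lengths, the gene window, the sequences counted and, added after seeing the data, the interval width, the unit of retention and matching on gene density.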

Results

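The series concerns ATR inhibition and cisplatin in Ewing sarcoma, and its design compares EWS-FLI binding in TC32 cells given siEWS-FLI with cells given siNEG. There was 1 CUT&Tag library in each group, so no difference below has a replicate check. The level of the fusion itself was not measured by these data. At the fusion's partner genes, the strongest siNEG summits were weak: 7 reads (95% interval 2.81 to 14.4) inside FLI1 on chromosome 11 and 12 reads (6.20 to 21.0) 5.93 kb from EWSR1 on chromosome 22. Neither gene had a siEWS-FLI summit within 50 kb.

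Fewer and smaller sites were called with siEWS-FLI. The siNEG library had 16284 intervals covering 5863 kb, and the siEWS-FLI library had 6370 covering 1543 kb, a ratio of 2.56 in number and 3.80 in length. A summit pileup of 50 raw reads or more was reached by 847 siNEG and 20 siEWS-FLI intervals. The median pileup was 8 reads with siNEG and 5 with siEWS-FLI. Intervals of exactly 200 bases, the narrowest listed, made up 71.4% of the siEWS-FLI list and 31.4% of the siNEG list. Among wider intervals the libraries had 11174 and 1823, a ratio of 6.13, and at −log10 q of at least 5 the ratio was 5.80. Reads outside the mitochondrial window stood at a ratio of 0.562, siEWS-FLI over siNEG, under the assumed genome size, so the counts of intervals were not taken at equal depth.

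Most siNEG sites were not called with siEWS-FLI. Of 16284 siNEG intervals, 2544 were shared (15.6%, 95% interval 15.1 to 16.2), against a mean of 0.158% and a maximum of 0.258% in random placements. Of 6370 siEWS-FLI intervals, 2617 were shared (41.1%, 39.9 to 42.3), against a random mean of 0.407%. Among siEWS-FLI intervals wider than 200 bases 93.3% were shared (92.0 to 94.3), and among those of exactly 200 bases 20.2% (19.0 to 21.4). Sharing followed siNEG strength, from 1.81% (1.41 to 2.33) in the weakest of 5 equal strength classes to 49.0% (47.3 to 50.8) in the strongest. When intervals were held to a reciprocal overlap of 50%, 7.88% of siNEG and 20.1% of siEWS-FLI intervals were shared.

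At the strongest sites near genes, both libraries had a peak and the siEWS-FLI peak was several-fold lower. At the end of LONP1, which encodes a mitochondrial protease, on chromosome 19 (5720080 to 5720779), the pileup was 801 reads with siNEG (746 to 858) and 78 with siEWS-FLI (61.7 to 97.3). At MBD3L1 on the same chromosome (8832076 to 8833063) it was 1095 (1031 to 1162) and 108 (88.6 to 130). ZNF333 had 682 and 52 reads, TSSC4 555 and 47, MTMR4 510 and 59, and TRIM41 570 and 123, all within 1 kb of a gene end. WDR5, a subunit of histone methyltransferase complexes, had 513 and 71 reads at an intergenic site 4.96 kb away, and CRYBA4 had 476 and 67 at one 42.2 kb away. The ratio of siEWS-FLI to siNEG pileup at these 8 sites ran from 0.0762 at ZNF333 to 0.216 at TRIM41. Of the other two of the 10 strongest shared sites, one differed little, with 413 (374 to 455) and 396 reads (358 to 437) inside SPTLC3 on chromosome 20 (13167154 to 13167511). The other, inside LOC102724250 on chromosome 1 (633843 to 634207), had 14364 (14130 to 14601) and 10220 reads (10023 to 10420), a ratio of 0.712. Pileups are raw, and of 676 shared sites with 50 or more siNEG reads 662 had a ratio under the 0.562 of reads outside the mitochondrial window, against a mean of 346 from counting error at that ratio alone. That count was chosen after seeing the data, and picking sites by siNEG pileup lowers the ratio by itself. Mitochondrial reads outside that window still enter the 0.562. Reads in the window itself stood at a ratio of 0.879, so others at a like ratio would put the nuclear ratio below 0.562. The mean of 346 would then be too low. The ratio of nuclear reads was not measured, so loss beyond depth at these sites is not settled by this count.

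**Figure D1:**
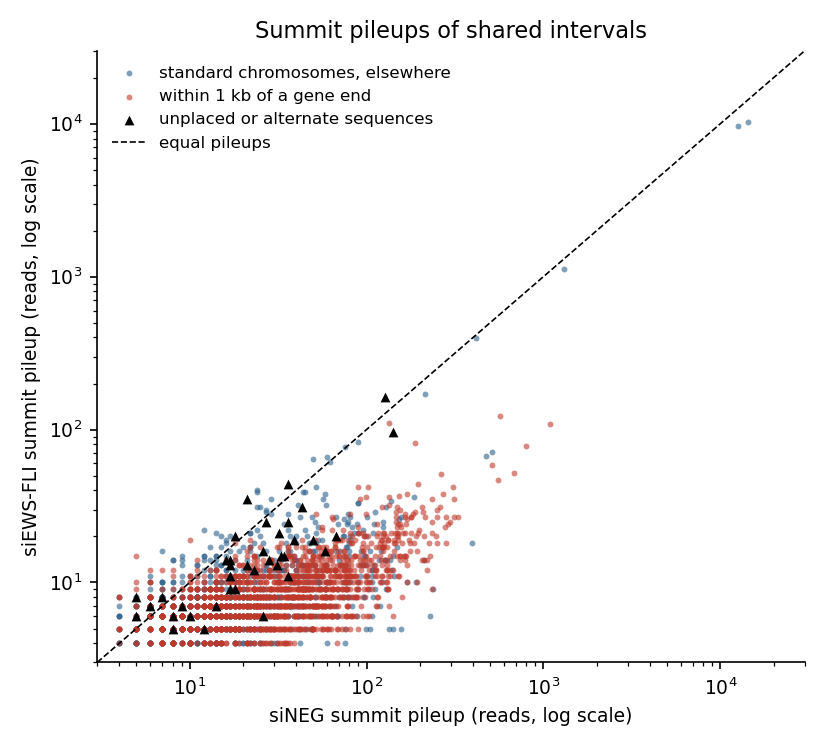
Summit pileup with siEWS-FLI against summit pileup with siNEG for shared intervals, in reads on log axes; each point is 1 siNEG interval, coloured by location, and the dashed line marks equal pileups. Gene-end sites with 100 or more siNEG reads lie near a median ratio of 0.111, and several unplaced sequences and sites such as SPTLC3 (ratio 0.959) lie near the line.

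The strongest siNEG-only sites included the end of ACTB, the gene of cytoplasmic beta-actin, with 158 reads (134 to 185) on chromosome 7 (5529704 to 5530238). A pileup of up to 19 reads would have stayed uncalled there with siEWS-FLI at the siNEG local background. APCDD1, an inhibitor of Wnt signalling, had 137 reads at a site inside the gene, and TAF13, which encodes a subunit of the transcription factor TFIID, had 99 reads at its end. ZC3H10 (101 reads) and C19orf47 (85) had gene-end sites, MYO15B (106) a site inside the gene, and CIROZ (130), SYT6 (117), PREX1 (107) and HMCN1 (90) intergenic sites within 50 kb. siEWS-FLI-only sites were far weaker, and the strongest had 9 to 12 reads. They lay at the ends of CDK12, a kinase of the RNA polymerase II tail (11 reads, 5.49 to 19.7), S100A4 (12), RBCK1 (11), E4F1 (10), DBR1 (9) and NARS2 (9). Sites inside GPM6B (10) and PTDSS2 (9) and intergenic sites near RAB6D (11) and TLR10 (10) completed the 10 strongest. Under the rule that counts intervals within 1 kb as shared, 25 of these 30 named intervals stayed in their class. The 10 shared ones cannot leave their class under this looser rule, so every change was of a siNEG-only or siEWS-FLI-only interval.

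Shared sites lay mostly at gene ends. Of shared siNEG intervals 65.4% (63.5 to 67.2) had a summit within 1 kb of a protein-coding gene end, against 30.7% (29.96 to 31.5) of siNEG-only and 8.18% (7.35 to 9.1) of siEWS-FLI-only intervals; random placement gave 2.88%. siEWS-FLI-only intervals lay inside genes in 44.3% and between genes in 47.5% of cases. Of gene-end siNEG intervals 28.3% (27.1 to 29.4) were retained, against 8.47% (7.95 to 9.02) of the others. Weighted to equal siNEG strength the shares were 20.6% and 11.0%, a difference of 9.62 percentage points (bootstrap 95% interval 8.54 to 10.7). At siNEG pileups of 20 to 49 reads, 51.9% of gene-end and 28.2% of other intervals were retained. Retention counts calls and not the signal kept. Among shared intervals the median pileup ratio was 0.261 at gene ends and 0.286 elsewhere at 20 to 49 siNEG reads. It was 0.149 and 0.185 at 50 to 99, and 0.111 and 0.110 at 100 or more. With both lists at the length of the siEWS-FLI list the difference was 15.7 points. The gene table gives no strand, so starts and ends of genes are pooled.

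**Figure D2:**
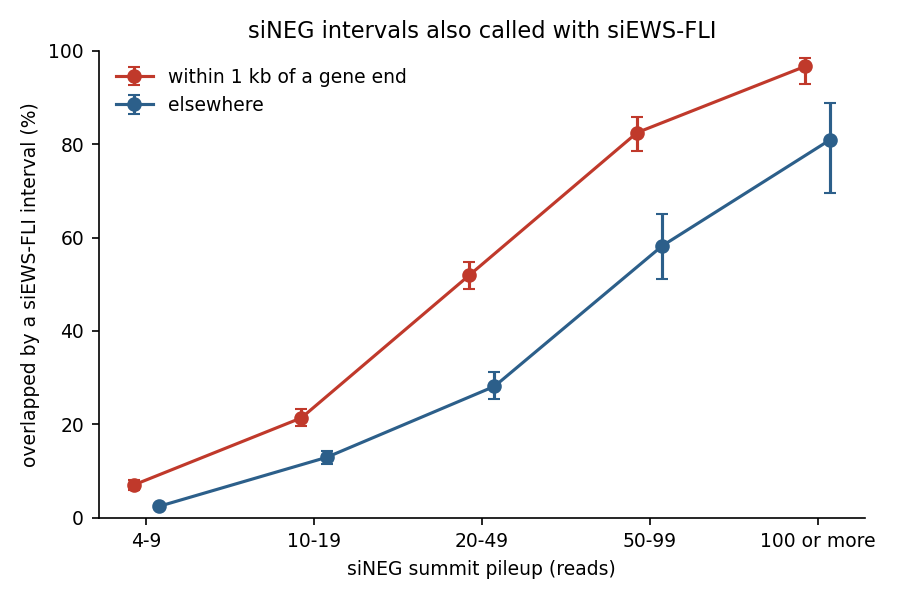
Share of siNEG intervals overlapped by a siEWS-FLI interval, in percent, by siNEG summit pileup in reads; red points are intervals within 1 kb of a gene end, blue points all others, and bars are Wilson 95% intervals. The share is higher at gene ends in each class, from 7.02% against 2.44% at 4 to 9 reads to 96.6% against 81.0% at 100 reads or more.

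Most genes reported as activated by EWS-FLI1 had a siNEG site within 50 kb, and few of these sites were called with siEWS-FLI. Of 30 genes 24 had a siNEG summit (80% against a random mean of 64.2%, 97.0th percentile), and 6 of the 24 also had a siEWS-FLI summit. LIPI and RBM11, named after their values were seen, have the same siNEG interval, so the 24 genes hold 23 strongest sites. That share of 25% (12.0 to 44.9) compares with a mean of 53.1% in random lists of equal siNEG strength and lay at the 0.075th percentile. Matched on gene density as well, a choice made after seeing the data, the random mean was 46.5% and the percentile 0.85. Of all 30 genes 26.7% had a siEWS-FLI summit, against 35.8% in lists of equal gene density (14.0th percentile). The share with a siNEG summit did not single out this list. Lists that ranked higher by it included ATR-CHK1 and ETS (each at the 99.995th percentile), housekeeping (99.965th), E2F (99.91th) and platinum repair (99.11th). Genes with siNEG summits only included CCND1, which encodes cyclin D1, with 61 reads (46.7 to 78.4) at an intergenic site 18.9 kb away on chromosome 11 (69621822 to 69622531). At the siNEG local background up to 12 siEWS-FLI reads would have stayed uncalled there. KDSR had 49 reads (36.3 to 64.8) at an intergenic site 10.4 kb away, and EGR2, an early growth response factor, had 26 (17.0 to 38.1) inside the gene. EZH2, the H3K27 methyltransferase, had 29 reads (19.4 to 41.6) at a site closer to CUL1. NR0B1, an orphan nuclear receptor, had 39 reads (27.7 to 53.3) 1.36 kb from the gene on chromosome X (30310593 to 30310884), not called with siEWS-FLI, whose summit of 5 reads lay at another position. SOX6 (33 siNEG reads) and PRKCB (34), both with sites inside the gene, also had siEWS-FLI summits of 5 reads at other positions. PHF19 alone kept its strongest site, with 55 reads (41.4 to 71.6) and 9 (4.12 to 17.1), nearest to C5. LOXHD1 and NPY1R had siEWS-FLI summits of 4 reads only, and ID2, PPP1R1A, HOXD13 and MYBL2 had none in either library. The low rank depends on the window and the assignment. The percentile was 8.91 within 100 kb and 15.3 with each summit given to its nearest gene alone, at any distance. Within 1 kb 0 of 11 genes kept a summit, so the percentile there, 6.67, was the lowest that list could reach. At 50 kb the retained share of 25% was the lowest of the 13 lists, with the repressed and epithelial lists next at 27.3%.

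The list of genes reported next to EWS-FLI1-bound GGAA microsatellites shares 15 genes with the activated list, so it is not independent of it. Of its 18 genes 16 had a siNEG summit and 5 of those a siEWS-FLI summit (31.2%, 14.2 to 55.6; random mean 58.2%, 0.965th percentile). Matched on gene density as well, the percentile was 2.9. CAV1, which encodes caveolin-1, had 27 siNEG reads and no siEWS-FLI summit. Within 1 kb 0 of 7 genes kept a summit, so the percentile of 12.8 was the lowest that list could reach.

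Of 17 genes reported as repressed by EWS-FLI1, 11 had a siNEG summit (64.7% against a random mean of 61.7%, 59.8th percentile), and 3 of these also had a siEWS-FLI summit (27.3%, 9.75 to 56.6; random mean 40.7%, 18.5th percentile). SPRY1 and TGFBR2 had 16 siNEG reads each and FOXO3 had 8, with no siEWS-FLI summit. ICAM1 shared a site nearest to MRPL4 (21 and 11 reads), and CDKN1A and TNC had siEWS-FLI summits of 6 and 5 reads at other positions. DKK1 and FOXO1 had siEWS-FLI summits of 4 reads only.

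Of 14 transcription factors of the Ewing regulatory circuit 13 had a siNEG summit (99.8th percentile), and 5 of them a siEWS-FLI summit (38.5%, 17.7 to 64.5; 22.6th percentile). EGR1 shared a gene-end site with 128 reads (107 to 152) with siNEG and 10 (4.80 to 18.4) with siEWS-FLI. The FOXM1 window shared a site nearest to ITFG2 (59 and 13 reads), and TCF4 had 5 reads in each library at different positions. MYCN (12 siNEG reads), BCL11B (13) and KLF15 (9) had no siEWS-FLI summit. With summits given to the nearest gene alone, at any distance, the share was 72.7% of 11 genes. That setting changed the distance limit as well as the assignment, so the higher share cannot be put down to the assignment alone.

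All 24 genes of the ATR-CHK1 pathway, which answers replication stress, had a siNEG summit, and 9 had a siEWS-FLI summit (37.5%, 21.2 to 57.3; random mean 50.7%, 8.13th percentile). ATR, the kinase at its head, had 12 siNEG reads (6.20 to 21.0) at its end on chromosome 3 (142578671 to 142578996), and CHEK1, its effector kinase, had 11 (5.49 to 19.7) at a site 32.5 kb away nearest to STT3A. Neither had a siEWS-FLI summit, and at the siNEG local background 4 reads would have stayed uncalled at either site. Elsewhere, 2673 siEWS-FLI intervals were called at 4 reads. RAD1 (26 siNEG reads), CDC25C (17), RPA2 (16) and HUS1 (13) likewise had siNEG summits only. The ATRIP window shared a site nearest to TMA7, with 155 (132 to 181) and 15 reads (8.40 to 24.7). RPA3 shared a site inside the gene (66 and 12 reads), and the CDK2 and RAD9A windows shared sites nearest to DGKA (56 and 7) and POLD4 (34 and 7). Within 1 kb, 20 members had a siNEG summit and 2 of them a siEWS-FLI summit. Those 2, named after their values were seen, were CLSPN (28 and 11 reads) and RAD17 (8 and 5).

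Genes that repair platinum adducts had siNEG summits in 24 of 26 cases, and 14 of the 24 had a siEWS-FLI summit (58.3%, 38.8 to 75.5; random mean 62.0%, 33.7th percentile). XPC, a damage sensor of nucleotide excision repair, shared a gene-end site with 162 reads (138 to 189) and 15 (8.40 to 24.7) on chromosome 3 (14178482 to 14178954), which also lies at the end of LSM3. The windows of ERCC1, PALB2 and REV3L shared sites nearest to POLR1G (121 and 16 reads), EARS2 (106 and 18) and SLC60A2 (58 and 9). ERCC4 (25 siNEG reads), ERCC3 (13) and REV1 (13) had no siEWS-FLI summit, and BRCA2 and SLFN11 had none in either library. Of 12 platinum transport and detoxification genes 10 had a siNEG summit and 5 of those a siEWS-FLI summit (50%, 23.7 to 76.3; 62.9th percentile). The SLC31A1 window, a copper transporter gene, shared a site nearest to CDC26 (30 and 6 reads), and GSR had 14 and MT1X 10 siNEG reads alone. MT2A and MT1E, named after their values were seen, have the same siNEG interval. With summits given to the nearest gene alone, at any distance, the retained shares were 16.7% for repair and 0% for transport.

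Replication genes regulated by E2F, ETS family genes and housekeeping genes all had siNEG summits, in 20 of 20, 18 of 18 and 24 of 24 cases. siEWS-FLI summits lay near 13 (65%, 43.3 to 81.9; 86.9th percentile), 12 (66.7%, 43.7 to 83.7; 90.7th) and 18 of them (75%, 55.1 to 88.0; 84.9th). PCNA, the replication clamp, shared a site 1.80 kb away nearest to TMEM230 (96 and 6 reads), and the AURKB and PLK1 windows shared sites nearest to VAMP2 (157 and 27) and DCTN5 (57 and 6). E2F1 had 35 siNEG reads and no siEWS-FLI summit. GABPA, an ETS factor of widely used promoters, shared its gene-end site with 85 reads (67.9 to 105) and 15 (8.40 to 24.7), and the ETV4 window shared one nearest to DHX8 (108 and 9). RPS19, a ribosomal protein gene, shared its gene-end site with 262 (231 to 296) and 51 reads (38.0 to 67.1). At −log10 q of at least 5 in both lists the shares were 23.5%, 23.1% and 50%. Of the strongest siNEG sites themselves 25%, 44.4% and 45.8% were shared, against random means of 33.6%, 27.6% and 50.5% matched on strength and location. These lay at the 15.5th, 96.85th and 27.7th percentiles, in a test chosen after seeing the data.

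Markers of other cell types served as background. Hepatocyte genes had siNEG summits in 7 of 16 cases (random mean 71.9%, 0.79th percentile), with 3 retained (42.9%, 15.8 to 75.0). Blood cell genes had them in 10 of 16, with 8 retained (80%, 49.0 to 94.3), and epithelial genes in 11 of 14, with 3 retained (27.3%, 9.75 to 56.6). CD3E and CD3D have the same shared site and FGA and FGB the same siNEG-only site, all named after their values were seen, so the 10 blood cell genes hold 9 strongest sites and the 7 hepatocyte genes 6. None of these genes had a siNEG summit within 1 kb: the window takes in sites of neighbours, such as that of RPS19 for CD79A, DHX38 for HP (126 and 21 reads) and CTDNEP1 for CLDN7 (166 and 15). Over all 20033 genes, 14389 had a siNEG summit within 50 kb and 8049 of these (55.9%) also a siEWS-FLI summit.

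**Figure D3:**
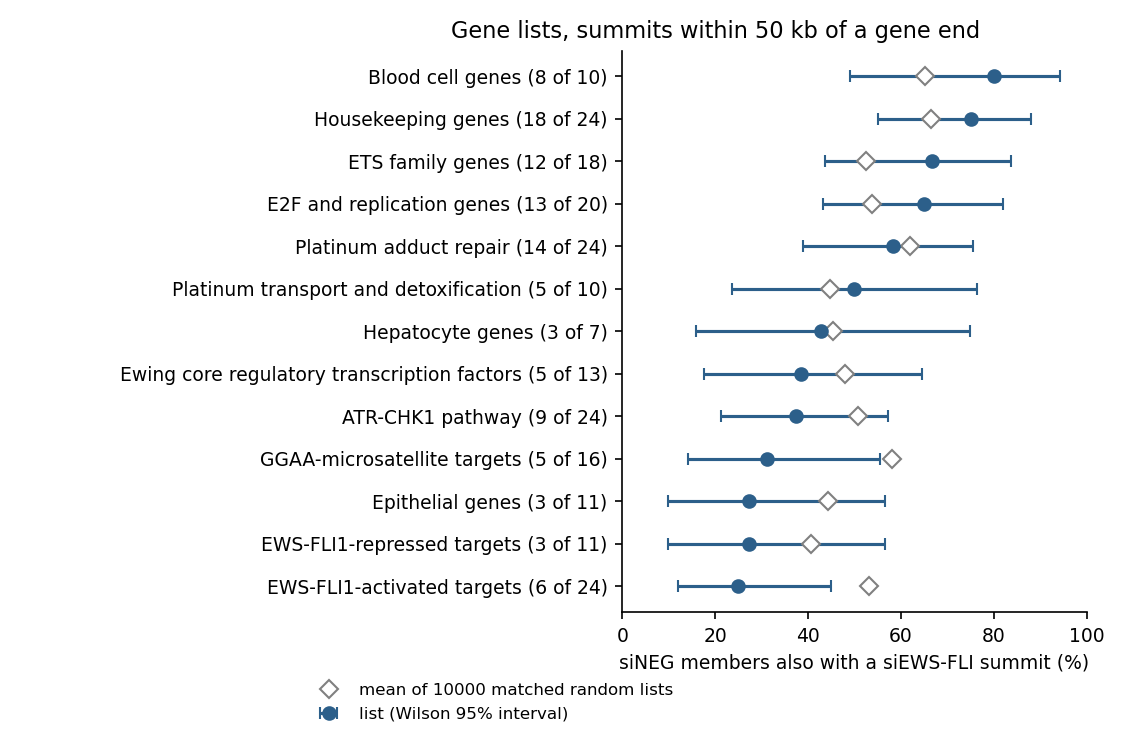
Percent of each list's members with a siNEG summit that also had a siEWS-FLI summit within 50 kb (blue points with Wilson 95% intervals, counts beside each name), and the mean of 10000 random lists matched on siNEG strength (diamonds). EWS-FLI1-activated targets lie lowest, at 25% against 53.1%, and blood cell genes highest, at 80% against 65.1%.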

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

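The tests of sequencing depth, of assay efficiency, of distal position and of stacked reads were chosen after the results they bear on had been seen; the others were set before. A pair of results stood out as signal on sequences that the comparisons left out. On unplaced and alternate sequences, 38 of 90 siNEG intervals were shared, and in 8 of them the siEWS-FLI pileup was the higher one. In the mitochondrial genome one 10 kb window held an implied 50.5% of all siEWS-FLI reads and 39.4% of siNEG reads under the assumed genome size.

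Fewer intervals and lower pileups were seen with siEWS-FLI. A single depth factor shared by gene-end and unplaced sites is argued against. At siNEG pileups of 20 or more the median pileup ratio was 0.222 at 1749 gene-end sites, with uncalled sites at their upper limit at the siNEG local background. It was 0.441 at 29 unplaced sites, with uncalled ones at 0, a ratio of medians of 0.504 (0.361 to 0.806). Whether unplaced sites follow nuclear depth was not tested, so lower nuclear depth as the whole cause is not settled. Of 38 shared unplaced intervals of any pileup, 8 had the higher pileup with siEWS-FLI. Picking sites by siNEG pileup lowers such ratios by itself. Lower efficiency of the assay in 1 library cannot be told apart from the siRNA with 1 library per group. Gene-end and other sites of 50 or more siNEG reads had medians of 0.143 and 0.169, with uncalled sites at their upper limit. The ratio of these medians was 0.846 (0.793 to 0.898), and a larger share of the other sites was uncalled. Retention near published EWS-FLI1-activated genes lay at the 0.075th percentile at equal strength and the 0.85th at equal strength and gene density. The percentile was not low within 100 kb (8.91) or by nearest gene at any distance (15.3). Within 1 kb, with 0 of 11 retained, the lowest rank possible was 6.67. Stronger loss near these genes, where it holds, is what less binding of the fusion would give. Lying within 1 kb of a gene end or not did not account for how few strongest sites were shared. Matched on that class and on strength, 1 of 24 strongest sites shared (4.17%, random mean 25.7%) lay at the 0.185th percentile. With each site counted once, 1 of 23 (random mean 23.3%) lay at the 0.7th. Distance beyond 1 kb was not matched, and the measure was the strongest site and not any summit within 50 kb. Distal position therefore remains open as a cause of the low retention at 50 kb. Reduced EWS-FLI binding beyond a library-wide difference remains a hypothesis that may hold for these genes.

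Intervals of exactly 200 bases made up most of the siEWS-FLI list. Stacked reads at one position may give them: of 2642 such intervals with 4 reads, 91.0% had the summit at the centre of a flat top, against 71.8% with siNEG. Picking the narrowest intervals at the smallest called pileup favours a flat top by itself, so this share is a weak test. Pileups above 400 show that repeated positions were kept. Whether they are narrow sites present in both libraries is not settled. At 4 to 8 reads 18.8% (17.6 to 19.9) of these intervals were shared, against 88.6% (86.2 to 90.7) of wider ones. Pileups within that range were not equal: of 2673 siEWS-FLI intervals with 4 reads, 2642 were 200 bases wide. Of siEWS-FLI intervals 10.5% were shared in the weakest of 5 strength classes and 91.7% in the strongest, so width and pileup were not separated. Binding that arises with siEWS-FLI was not tested.

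Gene-end intervals were retained more often at equal siNEG strength. Strength left within the 5 classes does not account for it, since 20 strength classes left 8.15 percentage points (7.12 to 9.18), and neither does interval width, since matching on width left 7.97 points (6.93 to 8.92). Cutting at open promoters that does not depend on EWS-FLI cannot be told apart from binding that outlasted the siRNA, for lack of a library without the antibody. Of the wider siEWS-FLI-only intervals, 26.8% (19.8 to 35.3) lay at gene ends. Retention counts calls and not the signal kept. With uncalled sites at their upper limit, gene-end and other sites of 50 or more siNEG reads had median pileup ratios of 0.143 and 0.169. Upper limits enter these medians unequally, since at 50 to 99 reads 82.5% of gene-end and 58.2% of other sites were shared. Among shared sites alone the medians were 0.149 and 0.185 at 50 to 99 reads, and 0.111 and 0.110 at 100 or more.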

How the results depend on the processing

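Intervals wider than 200 bases, the gene's strongest siNEG interval itself, each such interval counted once and matching on gene density as well were chosen after seeing the data; the others were set before the data were examined. No paired analysis was possible because each group had 1 library, and for the same reason no library was left out. Alternatives for GGAA repeats and ETS sites, and retention by at least 6 GGAA units, were not run, since no genome sequence was used here. siNEG exceeded siEWS-FLI in intervals under every alternative run, and gene-end intervals were retained more often under every alternative run. The causes of the moves below were not tested, except that stricter thresholds, wider intervals and smaller windows hold fewer sites by construction. Depth limits weak sites: the smallest pileup called was 4 reads in both libraries.

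Interval counts moved to 3642 with siEWS-FLI at −log10 q of at least 2, to 8803 and 1518 at 5 (ratio 5.80), and to 1823 with siEWS-FLI among wider intervals (ratio 6.13). The shared percentages of siNEG and siEWS-FLI intervals were 17.0 and 65.9 at −log10 q of at least 2, 14.5 and 85.4 at 5, 26.0 and 37.1 with only siNEG held to 5, 7.88 and 20.1 with reciprocal overlap, 13.8 and 35.2 with summits within 200 bases, 17.3 and 44.1 within 1 kb, 33.3 and 34.4 at equal list lengths, and 14.8 and 91.9 among wider intervals. The gene-end percentages of shared, siNEG-only and siEWS-FLI-only intervals were 72.8, 40.2 and 19.8 within 5 kb, 73.9, 37.9 and 12.9 for any gene type, and 69.7, 43.2 and 25.7 at −log10 q of at least 5. The gene-end difference in retention was 7.07 points at −log10 q of at least 5, 15.7 at equal list lengths and 7.66 among wider intervals.

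Of 74 list values under alternatives 35 stayed within the main interval and 60 lay below the main value. Within 1 kb, retained percentages were 0 for the activated, repressed, microsatellite and platinum transport lists, 10 for ATR-CHK1, 30 for platinum repair, 25 for E2F, 41.7 for ETS and 50 for housekeeping genes, and the other cell types gave no value. Within 100 kb the activated list was at 51.7 and epithelial genes at 58.3. By nearest gene, which set no distance limit, core transcription factors were at 72.7 and ATR-CHK1 and platinum repair at 16.7. Platinum transport and blood cell genes were at 0, E2F was at 42.9, and hepatocyte genes gave no value. At −log10 q of at least 5 the values were 5 for activated, 6.67 for microsatellite, 19.0 for ATR-CHK1, 14.3 for platinum transport, 23.5 for E2F, 23.1 for ETS and 50 for housekeeping genes. Among wider intervals they were 4.35, 9.09 and 6.67 for the activated, repressed and microsatellite lists, 37.5 and 22.2 for platinum repair and transport, 36.8 for E2F and 21.4 for ETS. For the strongest siNEG interval itself they were 4.17, 9.09, 6.25 and 15.4 for the activated, repressed, microsatellite and core factor lists, 20 for platinum transport, 25 for E2F, 45.8 for housekeeping and 9.09 for epithelial genes. The activated list's matched percentile was 8.91 within 100 kb and 15.3 by nearest gene at any distance. Within 1 kb, with 0 of 11 and 0 of 7 retained, the activated and microsatellite lists lay at 6.67 and 12.8, the lowest they could reach, so that window cannot test the 2.5 limit; with gene density matched as well they lay at 0.85 and 2.9, and under the other alternatives run both stayed below 2.5, at 0.075 and 0.175 with each strongest interval counted once.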

Other observations

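A small set of strong sites kept at least 0.5 times its siNEG pileup, and its members were named after their values were seen. Whether the reads at these sites came from EWS-FLI binding was not tested. Of 676 shared intervals with 50 or more siNEG reads, 16 had a siEWS-FLI pileup of at least 0.5 times the siNEG one. Besides the site inside SPTLC3, a subunit gene of serine palmitoyltransferase, one lay at the end of AMPD3, an AMP deaminase gene, on chromosome 11 (10507887 to 10508353; 134 and 110 reads). Several lay far from protein-coding genes: on chromosome 5 (49601478 to 49602551; 89 and 83 reads), on chromosome 17 (22521207 to 22521639; 12539 and 9614) and on chromosome 4 (49149097 to 49149853; 50 and 64). A further site inside LOC102724250 on chromosome 1 (629803 to 630109) had 1300 and 1115 reads. Pileups above 400, as there and at the chromosome 17 site, need repeated read positions.

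Retention differed between chromosomes. On chromosome 19, which is rich in genes, 29.7% of 1027 siNEG intervals were shared, and on chromosome 13 6.39% of 266. NPM1, the nucleophosmin gene, went against most shared housekeeping sites, with 5 siNEG reads (1.62 to 11.7) and 15 siEWS-FLI reads (8.40 to 24.7), and the counting intervals overlap. ELF1, an ETS factor gene, had 5 and 6 reads at its end.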
